A study of Homo sapiens with 4 samples.

How the data were processed

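RNA was sequenced from 4 libraries of established human multiple myeloma cell lines. MM.1S and RPMI8226 were each studied with OR-S1, a compound known here only by its code name and described by the series title as acting on EZH1 and EZH2, and without it. Per the labels' protocols, the treated cells received 1 μM OR-S1 for 72 h, both lines grew in RPMI1640 medium with serum, total RNA was isolated with a column kit and libraries followed a standard Illumina procedure. The labels do not say what the control cells received in place of the drug. Each of the 4 groups holds 1 library, so no difference within a line has a replicate check and no p-value was computed for it.

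The deposited values are TPM (transcript abundance, read counts divided by transcript length and scaled to a fixed total): each of the 4 columns sums to 1000000, and the unit was identified from that sum because the column headers name none. Per the submitters' processing notes the genome build was hg19. The aligner, the quantifier, the strand setting and the filters are not given in the sources used here. Each file lists the same 25341 genes with symbol, gene number and RefSeq transcripts, but no coordinates, so none are given. TPM values are relative: a change in one abundant transcript shifts the others, and a change in the total RNA of a cell cannot be seen.

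Of the 25341 entries, 7 carry no symbol and hold between 0.0008% and 0.0033% of a library. Another 2055 are short non-coding features (microRNA, small nucleolar and similar RNAs) that are shorter than a sequenced fragment, and these were left out with 0.554% to 0.825% of a library. Of 1 symbol listed more than once the entry with the higher mean was kept, which left 23278 genes. The response in each line was log2((OR-S1 TPM + 1) / (control TPM + 1)), a scale with a pseudocount of 1 that understates the change of low genes. A gene counted as expressed in a line at 1 TPM or above in at least one of its libraries, and as higher or lower when it changed at least 2-fold on that scale. A gene under 1 TPM in the control could pass only through its OR-S1 library and could not count as lower. Counts of higher genes in lists of low genes can therefore follow in part from the filter. Ratios of TPM are given without the pseudocount, and no ratio is given where a library lists a gene at 0.

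The overlap of both lines was set beside the overlap of independent lists (the product of the counts divided by the number of genes), and the Pearson and Spearman correlations of the log2 folds run across genes, which are not independent replicates. The lines share no control library. A test over both lines used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with the line as a block, an intensity trend and robust empirical Bayes moderation, 1 residual degree of freedom and two-sided Benjamini-Hochberg adjusted p-values over 14197 genes at 1 TPM or above in any library. It asks whether the mean change is large against the difference between the lines, so the lines stand in for replicates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 ran the rest.

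The design, the alternatives named below as fixed in advance and 40 gene lists with 1300 entries, of which 1299 were found in the files, were fixed before the data were examined. Some genes are in more than one list, such as DKK1 in the WNT antagonists, the WNT targets and the myeloma identity genes, and ID3 in the B cell and the TGF-beta and BMP genes. For each list and line the median log2 fold of the expressed members is given with its 95% order-statistic interval over genes and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. These percentiles describe these libraries and are not tests between conditions. A list is described as apart from random lists when its percentile lay outside the central 95%.

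Genes are named by a fixed rule: per line the 12 largest changes each way among genes at 5 TPM or above in the higher library, over both lines the 12 genes each way with the largest smaller change, up to 4 members of each list with the largest mean absolute log2 fold, the PRC2 core genes EZH1, EZH2, EED and SUZ12, 6 genes that changed in opposite directions, and the 5 smallest limma p-values each way. Symbols beginning with LOC, LINC, MIR or SNOR, those ending in -AS1, XIST and Y-linked genes were not named, and some genes that the rule selects are withheld and left out of the text. Genes named outside the rule are marked as chosen after their values were seen. Readthrough genes and families with near-identical copies (among them HLA, IFITM, CCL3, SPANX, MAGEA9 and histone genes) are uncertain, since reads can be assigned to the wrong copy.

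TPM carries no depth of its own, but multiplied by transcript length it fell on whole multiples of a step in each library. Lengths and GC content came from GENCODE v29 transcripts (GRCh38, a different build from hg19) matched by RefSeq accession for 23906 of the 25341 genes, and the step was found on low values of single-transcript genes between 400 and 2500 bases. Between 70.0% and 72.4% of these low values came out within 0.15 reads of a whole number, against 30.0% by chance for a step fixed in advance. The step and a length offset were chosen to make this share largest, so the chance level for the best choice is higher and was not computed. The estimated depth was 20.6 M reads (M, 1000000) for MM.1S with OR-S1, 14.99 M for its control, 13.7 M for RPMI8226 with OR-S1 and 15.7 M for its control. These are estimates. Intervals of TPM ratios are approximate 95% Clopper-Pearson intervals on such reads; they cover counting error only, and reads without molecular identifiers are not independent molecules.

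The steps were tested on simulated libraries drawn from the real levels and estimated depths, with 200 genes changed by known folds. With counting error and a line-specific spread of 0.26 on the log2 scale, 37 of 40 genes raised by 1.5 and 40 of 40 raised by 2 on the log2 scale reached 2-fold in MM.1S (11945 genes), and 37 of 40 and 40 of 40 did in RPMI8226 (12406 genes). For the test across both lines limma called all 40 genes of each size, and 26 of 13142 unchanged genes, so 11.5% of its calls were false, above the nominal share. The changed genes were at 5 TPM or above and had the same fold in both lines. The spread of 0.26 was also below the SD of the real log2 folds, 0.34 in MM.1S and 0.64 in RPMI8226. Recovery and false share in the real data may therefore differ. Of 200 random lists of 25 genes in RPMI8226 (12731 genes), 13 fell outside the central 95%, and all 50 lists raised by 0.5 lay above it. With unchanged levels and counting error alone, 20 simulated pairs gave on average 6.2 genes at least 2-fold higher and 4.8 lower in MM.1S, and 7.6 and 8.1 in RPMI8226 (21904 genes).

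Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 TPM, scaling to the upper quartile, to the same total and on the median fold, keeping the short features, summing entries of one symbol, a 1.5-fold threshold, and limma without the line block or without the trend and robust moderation. For limma, scaling on the median fold was replaced by centring the log2 values of each library on their median. Chosen after seeing the data were requiring the counting interval to exclude 1, removing the trend of the fold with GC content and length, thinning the deeper library of each line to the depth of the other, and leaving out genes that share reads.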

Results

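Gene expression was measured by RNA sequencing in MM.1S and RPMI8226, 2 cell lines established from patients with multiple myeloma, a tumour of antibody-secreting plasma cells. Each line was sequenced once after 72 h in 1 μM OR-S1 and once as a control, giving 4 libraries in 4 groups of 1. The files list TPM values, with 16924 genes above 0 in MM.1S with OR-S1, 15984 in its control, 17679 in RPMI8226 with OR-S1 and 16201 in its control. The estimated depth lay between 13.7 and 20.6 M reads. The treated MM.1S library was 1.37 times as deep as its control and the treated RPMI8226 library 0.87 times as deep. The 10 most abundant genes held 7.74% to 8.71% of each library. Across genes, log2 values of treated and control libraries correlated at a Pearson r of 0.991 in MM.1S and 0.965 in RPMI8226, and those of the control libraries of the lines at 0.84.

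The series concerns inhibition of the histone methyltransferases EZH1 and EZH2, the catalytic subunits of polycomb repressive complex 2 (PRC2), which places the repressive mark H3K27me3. Transcripts of the complex itself differed little. EZH1 (gene number 2145) stood at 30.9 TPM with OR-S1 and 29 in the control of MM.1S, and at 28.9 and 37.2 TPM in RPMI8226. EZH2 (2146) stood at 103.1 against 120.5 TPM in MM.1S and 67.0 against 65.1 in RPMI8226. EED (8726) stood at 46.6 against 50.2 and 32.0 against 32.9 TPM, and SUZ12 (23512) at 64.9 against 71.3 and 40.1 against 46.2 TPM. None of 13 PRC2 genes changed 2-fold in either line, with median log2 folds of -0.10 in MM.1S, which lay at percentile 1.54 of random lists, and -0.04 in RPMI8226, at percentile 39.7. Subunits of polycomb repressive complex 1 had higher medians, 0.25 over 23 genes in MM.1S and 0.26 over 24 in RPMI8226, at percentiles 99.2 and 99.5. Among them BMI1, a component of the ubiquitin ligase module, stood at 90.9 against 63.8 TPM in MM.1S and 67.8 against 30.8 in RPMI8226, and PHC1 at 5.99 against 3.88 and 9.29 against 1.63 TPM. CBX2, a reader of H3K27me3, was at 2.24 against 0.51 TPM in MM.1S. A list of 19 other chromatin modifiers, most of which act on H3K27, H3K4 or further histone sites, among them KMT2C and KMT2D, had a median of 0.10 in MM.1S and -0.23 in RPMI8226, the latter at percentile 0.74, and none changed 2-fold.

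The first question was which genes differed with OR-S1 in MM.1S. There 278 of 12590 expressed genes (2.21%) were at least 2-fold higher with OR-S1 and 34 (0.27%) at least 2-fold lower. IFITM1, an interferon-induced membrane protein, stood at 17.4 against 1.56 TPM. The lens crystallin gene CRYBA2 stood at 18.8 against 2.03 TPM, the germ cell transcription factor SOHLH1 at 7 against 0.45, the zinc finger gene ZNF467 at 11.4 against 1.88, the synaptic scaffold gene HOMER2 at 20.9 against 5.18, LY6E at 23.7 against 6.49, FBXO2 at 12.8 against 3.29, the chromatin organiser SATB1 at 16.1 against 4.77, SERINC2 at 10.9 against 3.02 and ID1, an inhibitor of helix-loop-helix transcription factors, at 38.7 against 12.6 TPM. Approximate 95% counting intervals of the TPM ratio ran from 5.68 to 22.9 for IFITM1, from 4.30 to 8.78 for ZNF467 and from 2.45 to 3.79 for ID1. Lower values were fewer and weaker. ADTRP stood at 4.47 against 10.3 TPM and TMEM150B at 1.68 against 5.23, while INSIG1, which holds back cholesterol synthesis, stood at 121.1 against 227.9 TPM, short of 2-fold. Most of the other genes with much lower values were readthrough genes or near-identical copies, such as FAM156B (listed at 0 against 5.62 TPM) and HIST1H2BH (2.62 against 11.5 TPM), and are uncertain. Of the 278 higher genes, 118 (42.4%) were under 1 TPM in the control and 31 were listed at 0 there. The count of higher genes was 702 with a pseudocount of 0.1 and 139 among genes reaching 5 TPM, and with the scaling that centres folds on their median it was 183. The count of lower genes was 82, 10 and 42 under these, 16 without genes that share reads and 105 with short features kept.

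The same comparison in RPMI8226 gave more genes: 1168 of 13256 (8.81%) were at least 2-fold higher with OR-S1 and 188 (1.42%) at least 2-fold lower. The spread of log2 folds over expressed genes was 0.64 (SD) in RPMI8226 and 0.34 in MM.1S. The largest changes were in genes that were silent or nearly so in the control. CCK, which encodes the peptide hormone cholecystokinin, stood at 60.9 TPM with OR-S1 and was listed at 0 in the control, as were TIMP3, an inhibitor of matrix metalloproteinases (24.9 TPM), and the homeobox gene DLX3 (15.4 TPM). The homeobox gene IRX3 stood at 38.7 against 0.11 TPM, CYP1A1, a target of the aryl hydrocarbon receptor, at 34.2 against 0.23, the BMP antagonist NOG at 22.7 against 0.13, the gelatinase gene MMP9 at 20.3 against 0.05, the transcriptional repressor SCRT2 at 21.1 against 0.26, the gap junction gene GJA1 at 23.4 against 0.41 and TGFBI, an extracellular matrix protein induced by TGF-beta, at 30.4 against 0.84 TPM. The cancer testis genes SPANXB1 (102.6 TPM) and MAGEA9B (16.04 TPM), both listed at 0 in the control, share reads with near-identical copies and are uncertain. Lower values were found for LTF, which encodes lactoferrin (1.32 against 11.8 TPM), the carbonic anhydrase CA9 (0.43 against 5.92), the calcium channel gene CACNA1D (1.21 against 8.12), VIPR2 (1.13 against 7.59), MYBPC2 (2.37 against 12.3) and the transcription factor KLF2 (14.9 against 60.1 TPM). Of the 1168 higher genes, 670 (57.4%) were under 1 TPM in the control and 189 were listed at 0 there. Among genes reaching 5 TPM, 559 were at least 2-fold higher and 125 lower. With a pseudocount of 0.1 the counts in RPMI8226 were 1619 higher and 329 lower.

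The next question was how far the lines responded alike. Of 11649 genes expressed in both, 88 were at least 2-fold higher in both (58 with folds centred on their median), where independent lists of these sizes would share 12.4, and 3 were lower in both, where they would share 0.2. These expected overlaps take no account of expression level. Higher genes were often low ones (42.4% in MM.1S and 57.4% in RPMI8226 were under 1 TPM in the control), so unrelated lists could share more than 12.4. The count of genes higher in both was 225 with a pseudocount of 0.1 and 45 with a filter at 5 TPM. Across genes the log2 folds correlated at a Pearson r of 0.385 and a Spearman rho of 0.334. Of the genes at least 2-fold higher in MM.1S, 83.6% had a positive log2 fold in RPMI8226, against 52.6% of all genes expressed in both. Among the shared genes with the largest changes were IFITM1 (163.5 against 29.5 TPM in RPMI8226) and IFITM2 (3.54 against 0.19 in MM.1S and 14.5 against 1.80 in RPMI8226), which belong to a family with near-identical copies and are uncertain. Others were ZNF467 (33.2 against 8.83 TPM in RPMI8226), ID1 (151.0 against 18.6 TPM in RPMI8226), SPINK2, a serine protease inhibitor (104.2 against 36.4 and 7.11 against 0.63 TPM), the lipid transfer gene STARD10 (20.1 against 6.55 and 8.05 against 1.93 TPM), RHBDF1 (6.12 against 1.5 and 2.20 against 0.16 TPM), GMPR (4.47 against 1.04 and 25.5 against 0.88 TPM) and ARHGEF40 (3.71 against 0.77 and 13.6 against 2.43 TPM). The 3 genes lower in both were ADTRP (13.0 against 32.0 TPM in RPMI8226) and the near-identical copies FAM156B and FAM86B2. INSIG1 was at 159.6 against 424.4 TPM in RPMI8226. TRIP13, which acts in the spindle checkpoint, was at 77.1 against 129.7 and 89.1 against 151.0 TPM, and ANKRD37, a gene induced by hypoxia, at 24.0 against 42.7 and 3.20 against 7.83 TPM.

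**Figure D1:**
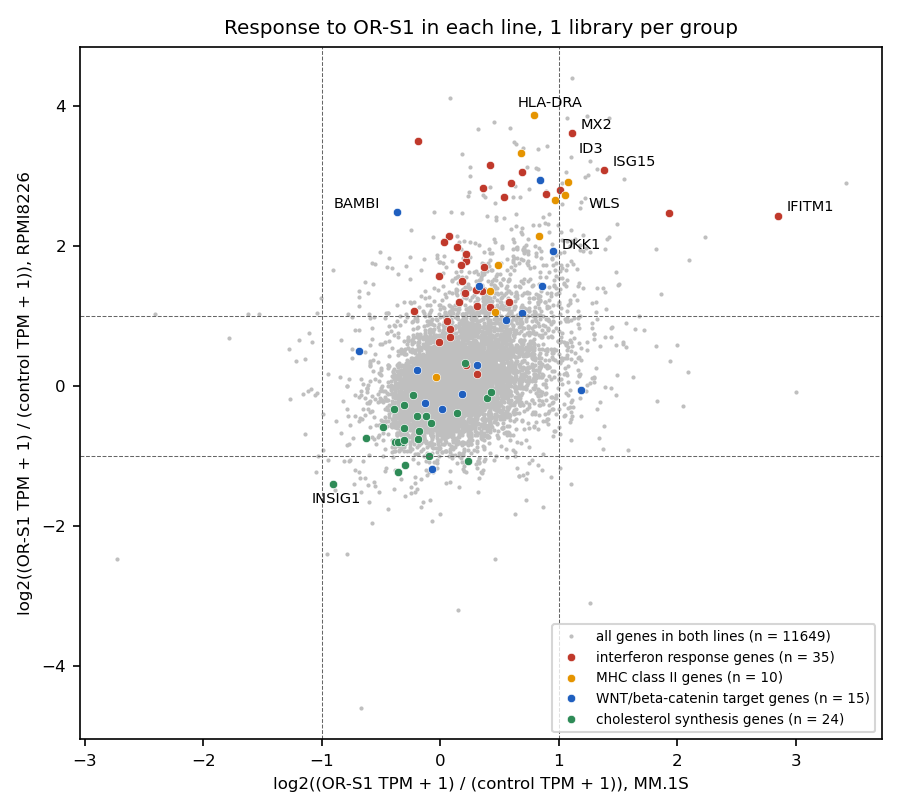
Each point is 1 of 11649 genes expressed in both lines, placed by its log2 fold (OR-S1 against control, pseudocount 1 TPM) in MM.1S on the x axis and in RPMI8226 on the y axis, with dashed lines at 2-fold and 4 gene lists in colour. Interferon response and MHC class II genes lie high on the RPMI8226 axis with smaller values on the MM.1S axis, and most cholesterol synthesis genes lie below 0 in both lines.

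Over both lines, limma called 0 of 14197 genes at an adjusted p under 0.05, with 1437 genes at an unadjusted p under 0.05, of which 1147 were higher and 290 lower, where 710 would be so by chance. With the log2 values of each library centred on their median, a correction other than centring the folds, limma called 1 gene, IFITM1. In that setting 1579 genes had an unadjusted p under 0.05, of which 710 were higher, so the excess of higher genes among these small changes turned round. Without such centring the smallest adjusted p in the main setting was 0.236, for IFITM1. Without the line block limma called 0 genes and 36 had an unadjusted p under 0.05, and without the trend and robust moderation it called 0 and 1272 did. In the simulated libraries with a line-specific spread 11.5% of limma calls were false, above the nominal share. The share in the real data, where the lines differ more, is not known. The counts adjusted over a list alone below may likewise hold more false calls than the nominal share. The genes with the smallest p-values were IFITM1, ZNF467, HIST1H4H, the metallothionein gene MT1X (18.7 against 7.99 TPM in MM.1S and 196.0 against 79.1 in RPMI8226) and LY86, a partner of the receptor CD180 (7.77 against 2.34 and 244.7 against 62.4 TPM), on the higher side, and FAM156B, ADTRP, ANKRD36BP2, INSIG1 and TRIP13 on the lower side.

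The series title names WNT signalling, a pathway in which secreted WNT proteins stabilise beta-catenin. WLS, which carries WNT proteins to the cell surface, was at 40.3 against 17.2 TPM in MM.1S and 5.91 against 0.19 in RPMI8226, and the ligand gene WNT10B at 3.29 against 0.38 and 3.75 against 1.71 TPM. Approximate counting intervals of the ratio were 2.04 to 2.64 and 10.9 to 107.3 for WLS, and 3.82 to 21.2 and 1.45 to 3.54 for WNT10B. On the scale with the pseudocount, 2 of 7 expressed genes of ligands and their secretion were at least 2-fold higher in MM.1S, WLS and WNT10B. In RPMI8226 1 of 10 was, WLS, and none was lower in either line. The medians were 0.66 (percentile 99.7) and 0.50 (percentile 85.3). In the list of receptors and co-receptors, which also holds the secreted R-spondins, 1 of 12 was higher in MM.1S (FZD2, 1.33 against 0.13 TPM). In RPMI8226 7 of 17 were, among them an R-spondin, LGR4 (3.35 against 0.42), FZD1 (3.69 against 0.92) and FZD7 (2.72 against 0.55 TPM). The medians of this list were 0.39 and 0.65 at percentiles 95.4 and 94.8. Most of the 7 were under 1 TPM in the control and passed the filter only through the OR-S1 library. Antagonist genes were apart from random lists in RPMI8226 and not in MM.1S. DKK1, a secreted inhibitor of the WNT co-receptors and itself a beta-catenin target, was at 17.1 against 8.41 TPM in MM.1S and 3.56 against 0.20 in RPMI8226. On the scale with the pseudocount none of 11 antagonists changed 2-fold in MM.1S (median 0.32, percentile 88.6). Without the pseudocount some did, such as DKK1 with a TPM ratio of 2.04. In RPMI8226 9 of 18 were higher and 1 lower with the pseudocount (median 0.89, percentile 99.5). The lower one was NKD2, at 72.5 against 169.4 TPM. Most of the 9 higher antagonists, such as DKK1 and SFRP1, were under 1 TPM in the RPMI8226 control. They passed the filter only through the OR-S1 library and could not count as lower, so the difference between the lines may follow in part from the filter. The list of beta-catenin pathway components also holds genes of WNT signalling without beta-catenin, such as CELSR2 and DAAM2, so its values mix both. Its medians were 0.25 over 28 genes in MM.1S (percentile 98.9) and 0.10 over 27 in RPMI8226 (percentile 72.2). In RPMI8226 2 members were at least 2-fold higher. TCF7, a nuclear partner of beta-catenin, was at 2.72 against 0.38 TPM, and DAAM2, named here after its values were seen, at 1.04 against 0.02 TPM.

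Genes known as WNT/beta-catenin targets differed more in RPMI8226, where 12 of 22 were at least 2-fold higher and 1 lower, with a median of 1.03 (95% interval -0.06 to 1.43, percentile 100). SOX9 was at 11.8 against 0.12 TPM, TWIST1 at 6.69 and listed at 0 in the control, BAMBI at 50.3 against 8.17 TPM and CD44 at 1.36 against 0.15 TPM. The lower one was MYC, at 425.3 against 971.1 TPM. In MM.1S 1 of 17 was at least 2-fold higher, CCND1, which encodes cyclin D1 (15.8 against 6.40 TPM), none was lower, and the median was 0.23 (interval -0.13 to 0.69, percentile 94.97), inside the central 95% of random lists. CCND1 was at 17.7 against 18.6 TPM in RPMI8226. AXIN2, a direct target chosen here after its values were seen, was at 11.02 against 9.23 TPM in MM.1S and 0.99 against 0.78 in RPMI8226. By limma 0 of 24 targets passed over all genes tested and 5 when adjusted over the list alone (smallest adjusted p 0.021), and for the ligands 0 of 11 and 3 (0.043). The RPMI8226 median of the targets was 1.44 with a pseudocount of 0.1 and 0.49 with no filter on low values. Most of the 12 higher targets, such as SOX9 and CD44, were under 1 TPM in the control and passed the filter only through the OR-S1 library.

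**Figure D2:**
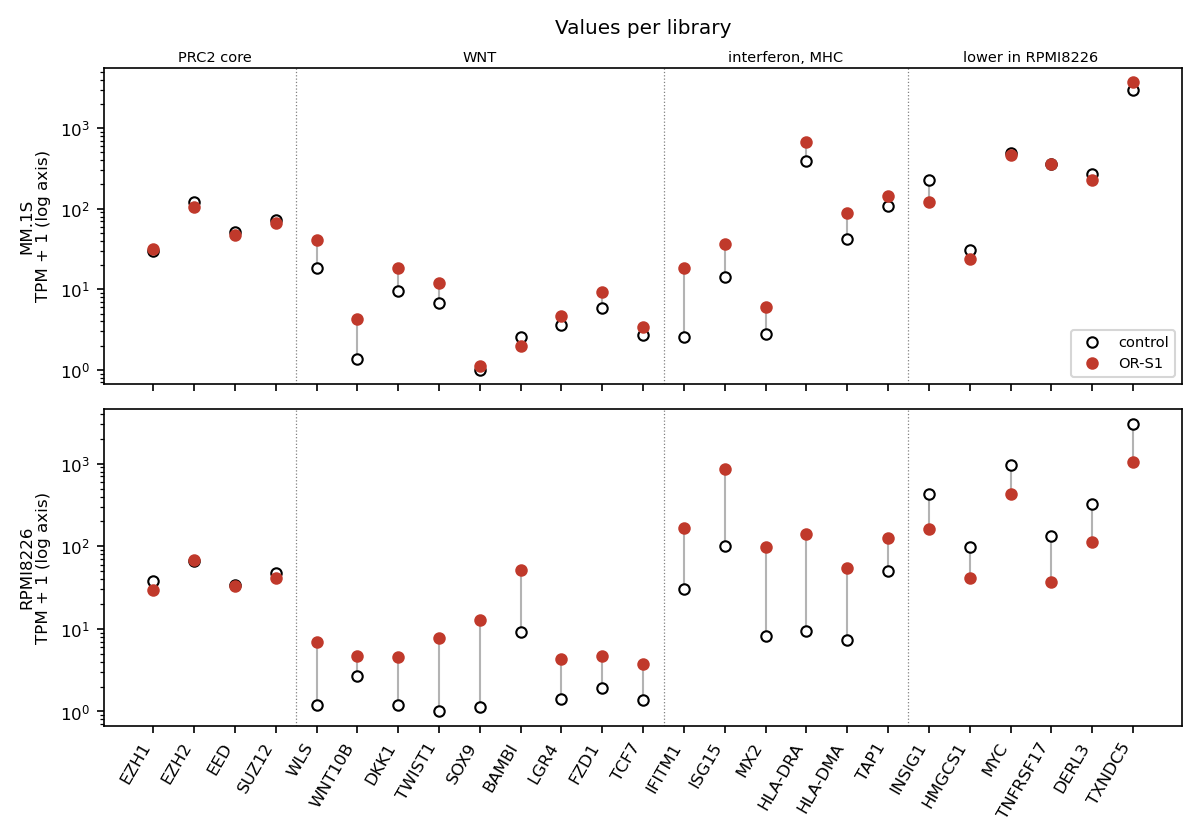
TPM + 1 on a log axis for 25 genes in the control (open circles) and OR-S1 (filled circles) library of MM.1S (top) and RPMI8226 (bottom), 1 library per circle. The PRC2 core genes lie close together in both lines, most of the WNT, interferon and MHC genes shown lie further apart in RPMI8226, with IFITM1 and WNT10B further apart in MM.1S, and MYC lies at 971.1 TPM in the control and 425.3 TPM in the OR-S1 library of RPMI8226.

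Interferon response genes were higher in RPMI8226, where 36 of 43 were at least 2-fold higher and none lower (median 1.88, interval 1.37 to 2.21, percentile 100). ISG15, a ubiquitin-like protein induced by interferon, was at 854.5 against 100.5 TPM and MX2, an antiviral GTPase, at 98.0 against 7.10. In MM.1S 5 of 37 were at least 2-fold higher and none lower (median 0.31, interval 0.18 to 0.42, percentile 99.6). The 5 were IFITM1, IFITM2, ISG15 (35.9 against 13.2 TPM), MX2 (5 against 1.78) and XAF1 (3.76 against 1.37), and all 5 were also at least 2-fold higher in RPMI8226. XAF1 is named here after its values were seen. By limma 0 of 45 passed over all genes and 2 adjusted over the list alone (smallest adjusted p 0.00075). These 2 were IFITM1 and IFITM2, which belong to a family with near-identical copies and are uncertain. MHC class II genes, which present peptides to helper T cells, moved the same way. In RPMI8226 11 of 12 were at least 2-fold higher (median 1.93, interval 1.21 to 2.91, percentile 100), with HLA-DRA at 137.9 against 8.48 TPM and HLA-DMA at 53.8 against 6.27. In MM.1S 3 of 12 were, among them HLA-DMA (88.6 against 41.4 TPM) and HLA-DMB (28.7 against 13.3 TPM), and the median was 0.81 (interval 0.46 to 1.05, percentile 100), with HLA-DRA at 669.3 against 387.95 TPM. When genes that share reads were left out the MM.1S median was 0.42. That value covers only the few list members that are not HLA genes and says nothing on the HLA genes. MHC class I and antigen processing genes had medians of 0.27 over 23 genes in MM.1S, none of them 2-fold, and 0.36 in RPMI8226, where 4 were at least 2-fold higher, both at percentile 100. HLA-B was at 2298 against 1305 and 3275 against 1459 TPM, and TAP1, a peptide transporter, at 144.3 against 108.5 and 126.7 against 49.4 TPM. Adjusted over the list alone, 6 of 14 class II and 6 of 23 class I genes passed in limma, and 0 over all genes. HLA genes are polymorphic and similar to each other, so single HLA values are uncertain. Myeloid cell markers moved with these genes in RPMI8226, with a median of 1.30 and 6 of 11 at least 2-fold higher (percentile 99.9), such as LYZ at 1.87 against 0.08 TPM, CD14 at 3.65 against 0.44 and AIF1 at 9.14 against 2.42. CD68, chosen after its values were seen, was at 67.7 against 43.9 TPM. The list had a median of 0.04 over 3 genes in MM.1S (-0.05 with centred folds).

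Developmental regulators known as polycomb targets were also higher. In RPMI8226 19 of 50 such transcription factors were at least 2-fold higher and 1 lower (median 0.80, interval 0.42 to 1.05, percentile 99.9), and in MM.1S 1 of 32 was higher (median 0.39, interval 0.17 to 0.51, percentile 98.9). The 4 with the largest mean change, IRX3, DLX3, SOX9 and TWIST1, were at least 2-fold higher in RPMI8226, while in MM.1S IRX3 and DLX3 were listed at 0 in both libraries and TWIST1 was at 11.1 against 5.75 TPM. HOX genes, which set position along the body axis, were at least 2-fold higher in 8 of 10 in RPMI8226 (median 1.16, percentile 98.6), among them HOXB6 (5.29 against 0.15 TPM), HOXC4 (3.55 against 0.14) and HOXB7 (5.86 against 1.52), and in 1 of 5 in MM.1S (median 0.64, percentile 96.6). The list names 39 HOX genes, and those not counted did not reach 1 TPM in the line. Most of the 8 were under 1 TPM in the control, passed the filter only through the OR-S1 library and so could not count as lower. The same holds for the transcription factors counted as higher in RPMI8226. With no filter on low values the RPMI8226 medians were 0.63 for the HOX genes and 0.37 for the transcription factors. The 1 in MM.1S was HOXA10, named here after its values were seen, at 2.81 against 0.85 TPM. TGF-beta and BMP pathway genes were higher in both lines, with medians of 0.58 over 19 genes (3 at least 2-fold higher) in MM.1S and 0.61 over 25 (9 at least 2-fold higher) in RPMI8226, at percentiles 100 and 99.9, and none lower. The 3 were ID1, ID3 (195.8 against 90.9 TPM in MM.1S and 487.9 against 49.7 in RPMI8226) and NOG (3.69 against 1.17 TPM in MM.1S), and each was also higher in RPMI8226, where SMAD6, an inhibitor of BMP signalling, was at 15.3 against 2.51 TPM. Adjusted over the list alone limma called 3 of 26 (smallest adjusted p 0.023), and 0 over all genes.

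Other groups were lower. Genes of cholesterol synthesis had medians of -0.27 over 24 genes in MM.1S (interval -0.36 to -0.10), none 2-fold lower, and -0.63 in RPMI8226 (interval -0.81 to -0.39), where 4 were at least 2-fold lower, both at percentile 0.0. HMGCS1, the enzyme before the rate-limiting step, was at 22.9 against 29.6 TPM in MM.1S and 40.3 against 96.8 in RPMI8226, and LSS at 95.6 against 118.1 and 74.6 against 164.2 TPM. By limma 0 of 24 passed over all genes and 8 adjusted over the list alone (smallest adjusted p 0.014). MYC and its targets had medians of -0.24 over 43 genes in MM.1S and -0.28 in RPMI8226, both at percentile 0.0, and MYC itself, at 467.3 against 491.2 TPM in MM.1S, was the 1 gene 2-fold lower in RPMI8226. NOLC1 and CAD were at 140.5 against 181.6 and 34.7 against 44.1 TPM in MM.1S, and at 82.2 against 149.3 and 45.8 against 83.2 in RPMI8226. By limma 0 of these 43 genes passed over all genes or adjusted over the list alone, and 16 had an unadjusted p under 0.05.

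Plasma cell genes differed in RPMI8226. There 6 of 31 were at least 2-fold lower and 1 higher, with a median of -0.41 (interval -0.92 to -0.25, percentile 0.0). TNFRSF17, which encodes the plasma cell antigen BCMA, was at 36.4 against 131.7 TPM, TXNDC5, a protein disulfide isomerase, at 1058 against 3029, DERL3 at 111.6 against 323.9 and BHLHA15, a regulator of secretory cells, at 43.3 against 126.2 TPM. In MM.1S the same 4 were at 359.0 against 359.7, 3716 against 2984, 228.9 against 271.5 and 39.2 against 45.5 TPM, the list's median was 0.03 (percentile 94.4) and -0.06 with folds centred on their median, and 1 of 31, NCAM1 (6.36 against 2.44 TPM), was at least 2-fold higher. Genes of the unfolded protein response had medians of -0.03 over 29 genes in MM.1S (percentile 28.3), with VLDLR (4.76 TPM with OR-S1) the 1 gene 2-fold higher, and -0.38 over 28 in RPMI8226 (percentile 0.0), with ERN1, a sensor of this response, at 17.7 against 42.6 TPM and the 1 gene 2-fold lower. B cell genes were higher, with medians of 0.42 over 20 genes in MM.1S (2 higher, 1 lower, percentile 99.8) and 0.54 over 23 in RPMI8226 (8 higher, percentile 100). The transcriptional repressor BCL6 was at 3.84 against 1.40 and 6.18 against 1.31 TPM, and FCRLA at 10.4 against 4.79 and 26.99 against 8.44 TPM.

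**Figure D3:**
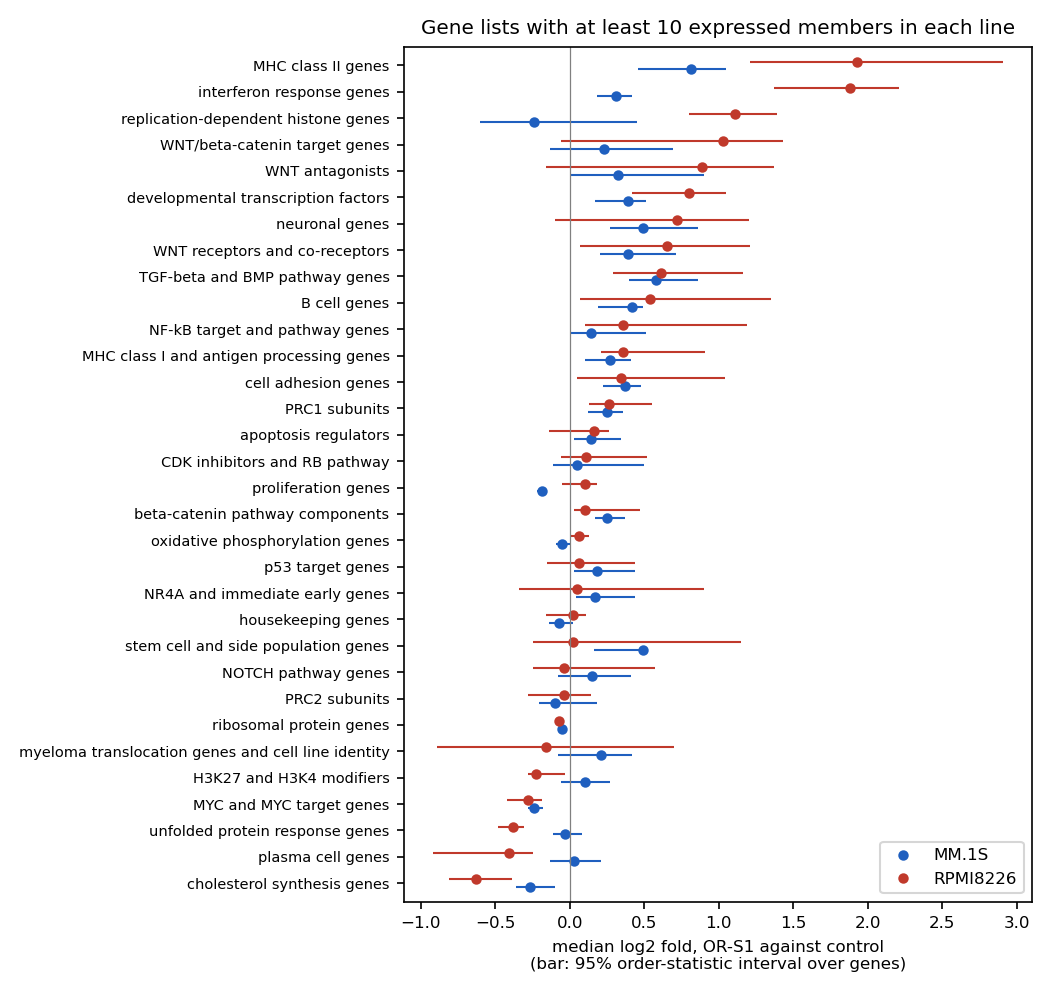
Median log2 fold of the expressed members of each gene list with at least 10 such members in each line, in MM.1S (blue) and RPMI8226 (red), with bars for the 95% order-statistic interval over genes, which are not replicates. MHC class II and interferon response genes have the highest medians in RPMI8226 (1.93 and 1.88), and cholesterol synthesis genes the lowest (-0.63).

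The series title also names stem cells. Genes linked to stem cells and the dye-excluding side population had a median of 0.49 over 12 genes in MM.1S (percentile 99.8) with 1 at least 2-fold higher, SMO (1.98 against 0.38 TPM), named here after its values were seen. In RPMI8226 the median was 0.02 over 15 (percentile 19.7; -0.03 with centred folds), with 6 at least 2-fold higher and 1 lower. The higher ones included the aldehyde dehydrogenase gene ALDH1A1 (2.85 against 0.10 TPM), KIT (3.23 against 0.34) and CD44, and the lower one was the telomerase gene TERT, at 5.08 against 15.7 TPM. These values are means over all cells of a culture and do not count stem cells. Proliferation genes had a median of -0.19 over 47 genes in MM.1S (interval -0.22 to -0.15, percentile 0.0) and 0.10 in RPMI8226 (interval -0.05 to 0.18, percentile 98.4). None of them changed 2-fold on the scale with the pseudocount. Cyclin-dependent kinase inhibitors and the RB pathway had medians of 0.05 over 18 genes in MM.1S (percentile 61.7; -0.04 with centred folds), 2 of them higher (CCND1 and CDKN1C, 17.5 against 7.77 TPM), and 0.11 over 20 in RPMI8226 (percentile 90.4), 1 of them higher (CDKN1A, which encodes p21, at 63.3 against 28.6 TPM). Apoptosis regulators had medians of 0.14 over 26 and 0.16 over 28 genes (percentiles 96.7 and 97.2), with 0 and 3 at least 2-fold higher. The 3 were BMF, a pro-apoptotic BH3-only protein (44.8 against 12.04 TPM), the death ligand TNFSF10 (21.5 against 6.81) and BIRC3 (4.02 against 1.05). For p53 targets the medians were 0.18 over 24 genes (percentile 96.2, none 2-fold) and 0.06 over 23 (percentile 56.5, 4 at least 2-fold higher).

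Housekeeping genes had medians of -0.07 over 24 genes in MM.1S (percentile 19.4) and 0.02 in RPMI8226 (percentile 75.5; -0.03 with centred folds), ribosomal protein genes -0.05 and -0.07 over 57 (percentiles 75.3 and 12.7), and oxidative phosphorylation genes -0.05 and 0.06 over 37 (percentiles 60.6 and 96.2), and none of these changed 2-fold. T and NK cell markers had medians of 0.34 over 7 genes in MM.1S and -0.09 over 7 in RPMI8226 (percentiles 74.2 and 10.4), 0 and 1 of them at least 2-fold higher, with CD3E at 13.1 against 9.85 and 1.61 against 0.16 TPM. Erythroid and platelet markers had medians of 0.27 over 4 and 0.66 over 3 genes (percentiles 69.7 and 95.02), 0 and 1 of them at least 2-fold higher. The globin gene HBA1, which has a near-identical copy and is uncertain, was at 84.4 against 31.1 TPM in RPMI8226, and HBD at 101.3 against 70.7 TPM in MM.1S. Stromal, endothelial and epithelial markers had medians of 0.40 over 5 and 0.81 over 9 (percentiles 72.2 and 94.5), 0 and 4 of them at least 2-fold higher, with COL1A2 at 3.92 TPM in RPMI8226 with OR-S1 and listed at 0 in its control.

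Whether the lines responded differently could only be described, since 1 library per group leaves no error for that difference. At least 2-fold higher in one line and at least 2-fold lower in the other were 8 of 11649 genes, where independent lists would give 3.5. The count was 4 with folds centred on their median, 4 with the GC and length trend removed, 4 without genes that share reads, 2 among genes reaching 5 TPM and 31 with short features kept. They included the uncharacterised gene ZASP (11.8 against 4.36 TPM in MM.1S and 0.26 against 9.87 in RPMI8226), FAM231D (0.34 against 2.88 and 5.68 against 2.28) and HIST1H4E (listed at 0 against 2.07, and 7.21 against 3.05 TPM). The readthrough genes COMMD3-BMI1, BLOC1S5-TXNDC5 and APITD1-CORT were also among them, and their reads overlap those of the genes they join.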

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

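In this part the tests for myeloid cells, for cells in S phase and for RNA without a poly(A) tail were chosen after the result was seen, as were the thinning to equal depth and the removal of the trend with GC content and length. The differences between the lines given here were not tested, since each group holds 1 library.

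Genes at least 2-fold higher in one line and at least 2-fold lower in the other numbered 8, among them PMCH, chosen after its values were seen (listed at 0 against 1.01 TPM in MM.1S, and 1.39 TPM against a control listed at 0 in RPMI8226). Proliferation genes had a median log2 fold of -0.19 in MM.1S and 0.10 in RPMI8226. Genes of myeloma translocations and cell line identity had medians of 0.21 over 18 genes in MM.1S (percentile 99.4), 1 of them at least 2-fold higher, and -0.16 over 20 in RPMI8226 (percentile 1.81), 4 higher and 2 lower. Among the 4 higher genes in RPMI8226 was FGFR3, at 4.68 against 0.53 TPM. MAF, chosen after its values were seen, was at 333.8 against 705.9 TPM in RPMI8226 and 364.1 against 291.9 in MM.1S. Replication-dependent histone genes had medians of -0.24 over 20 genes in MM.1S (percentile 0.0), 1 higher and 3 lower, and 1.11 over 23 in RPMI8226 (percentile 100), 16 higher and 1 lower. The MM.1S median was 0.07 with no filter on low values and 0.45 with a filter at 5 TPM. By limma 0 of 25 histone genes passed over all genes and 3 adjusted over the list alone.

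Values outside the main measurement also stood out. Of the 7 entries without a symbol, 1 was at least 2-fold higher in RPMI8226, at 14.05 against 6.21 TPM. Among short non-coding features 80 of 251 were at least 2-fold higher and 71 lower in MM.1S, and 58 of 195 were higher and 76 lower in RPMI8226. Features shorter than a fragment are poorly measured, and these values have no replicate.

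The first pattern weighed was that most 2-fold changes were upward, 89.1% in MM.1S and 86.1% in RPMI8226. Scaling to the upper quartile or on the median fold left at least 81.3% upward in either line, equal depth over 20 thinnings left 88.8% in MM.1S and 86.0% in RPMI8226, and removing the trend with GC content and length left 90.1% and 84.6%. The values for scaling and for depth argue against each of these as the whole cause of the 2-fold changes being mostly upward, but not of smaller changes. The trend with GC content and length was fitted to folds limited to 2-fold, and the mean fold was kept. Its removal could therefore take away only part of larger folds and does not decide on GC content and length. With the log2 values of each library centred on their median, 710 of 1579 genes at an unadjusted p under 0.05 in limma were higher, against 1147 of 1437 as deposited. The drug treatment is the difference the design names and may be the source, and a difference between the single cultures stays open.

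The second pattern was the higher interferon response genes in RPMI8226. Scaling left their median at 1.82 or above, which argues against scaling. Myeloid cells would bring abundant transcripts of their own, and the largest rise among 9 such transcripts, 1.79 TPM for LYZ, was 0.24% of the 754 TPM rise of ISG15. Over all expressed members of the myeloid list the largest rise, 23.8 TPM for CD68, was 3.16% of it, and both values argue against such cells. A response to the treatment may be the source, as a hypothesis from 1 library per group, and a difference in the handling of single cultures stays open.

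The third pattern was the higher histone genes in RPMI8226. Reads moved between near-identical copies would leave the sum alone, and the summed TPM of 72 histone genes was 1161 against 506.5, a ratio of 2.29 (164.6 against 142.5 in MM.1S). More cells in S phase would raise S-phase genes, and 18 of them had a median of -0.13 (interval -0.27 to 0.10). These values argue against both. More RNA without a poly(A) tail in the treated library may be the source and stays open, as does a response of RPMI8226 to the treatment: of the RNAs of this kind that are not short features only RMRP and RPPH1 were expressed, with a median log2 fold of 1.08, too few to decide, while 114 such RNAs with the poorly measured short features had -0.61 (interval -1.01 to -0.22), which points the other way.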

How the results depend on the processing

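The alternatives on the counting interval, the GC and length trend, the equal depth and the genes sharing reads were chosen after seeing the data. A count moved here when it left the range within 1.5 times its value, and the cause was not tested unless given. With a pseudocount of 0.1, 702 genes were at least 2-fold higher and 82 lower in MM.1S, 329 lower in RPMI8226, 225 higher in both, 10 lower in both and 24 opposite, and the median of the WNT targets in RPMI8226 was 1.44; with 0.5 the counts were 489, 53, 158 higher in both and 7 lower in both. A smaller pseudocount enlarges the folds of low genes by construction. A filter at 5 TPM, which leaves fewer genes, gave 139 and 10 in MM.1S, 559 and 125 in RPMI8226, 45 higher and 1 lower in both and 2 opposite. A 1.5-fold threshold, looser by construction, gave 1170 and 139, 2161 and 759, 442 and 31 in both, and 64 opposite. Centred on the median fold, 183 genes were higher in MM.1S, 58 higher and 5 lower in both and 4 opposite. With the log2 values of each library centred on their median instead, limma called 1 gene, IFITM1 (1579 at an unadjusted p under 0.05, 710 of them higher). With short features kept, which adds features, 105 were lower in MM.1S, 20 lower in both and 31 opposite. With the counting interval required, 5 were opposite; with the GC and length trend removed, 1 was lower in both and 4 opposite; without genes sharing reads, 16 were lower in MM.1S, 1 lower in both and 4 opposite. The histone median in MM.1S turned from -0.24 to 0.07 with no filter and 0.45 with a filter at 5 TPM. The correlation between the lines lay between 0.301 and 0.404, and limma called 0 genes in the other settings it was run under (both pseudocounts, both filters, 2 further scalings, short features kept, symbols summed, no line block, no trend). Of the 278 and 1168 higher genes, 254 and 1085 were also higher with the GC and length trend removed and 250 and 1144 at equal depth. Of 958 list medians under alternatives, 929 stayed within their interval, 27 moved and 2 reversed. A median counted as reversed only when it changed sign in a list apart from random lists. Medians of other lists that changed sign, such as those of plasma cell genes in MM.1S and housekeeping genes in RPMI8226, are not among the 2. Of 3228 such values of the genes named, 3164 stayed on the same side of the 2-fold limit and 64 crossed it, 24 of them with a pseudocount. Among values at least 2-fold changed, 0 reversed in sign. An alternative that used intervals of the deposited values was not run, since the files hold none, and leaving out a replicate does not apply with 1 library per group. Depth limits low genes, since 1 read over 1 kb of transcript is worth 0.091 to 0.128 TPM.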

Other observations

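The test of interferon transcripts and the test of silent genes given below were chosen before their results were seen. Cell adhesion genes had medians of 0.37 over 28 genes in MM.1S (percentile 99.99, 2 at least 2-fold higher) and 0.34 over 32 in RPMI8226 (percentile 98.8, 10 higher and 1 lower). Eph receptors and ephrins, which act in contact between cells, had medians of 0.51 over 6 genes (percentile 90.9, none 2-fold) and 0.84 over 13 (percentile 99.4, 6 higher), with EPHB2 at 48.6 against 17.9 TPM and EPHB6 at 5.41 against 0.07 in RPMI8226. NF-kB genes had medians of 0.14 over 23 genes (percentile 88.2, 2 higher and 1 lower) and 0.36 over 26 (percentile 99.6, 8 higher and 1 lower). CCL3, a chemokine with near-identical copies and therefore uncertain, was at 1030 against 490 TPM in MM.1S and 3.91 against 0.48 in RPMI8226, and the receptor CD40 at 15.2 against 3.29 TPM in RPMI8226. Adjusted over the list alone limma called 1 of 27 NF-kB genes, 1 of 25 B cell genes and 1 of 5 erythroid and platelet markers, and 0 over all genes.

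NR4A and immediate early genes had medians of 0.17 over 24 genes in MM.1S (percentile 98.1, none 2-fold) and 0.05 over 27 in RPMI8226 (percentile 62.9, 6 higher and 2 lower), with FOS at 60.7 against 20.5 TPM and SGK1 at 5.43 against 0.79 in RPMI8226. NOTCH pathway genes had medians of 0.15 over 13 and -0.04 over 17 genes (percentiles 67.5 and 16.6), with 0 and 1 at least 2-fold higher. Neuronal genes had medians of 0.49 over 10 (percentile 96.7, 1 higher; 0.07 with no filter on low values) and 0.72 over 16 (percentile 99.2, 4 higher), with DCX at 2.47 against 0.15 TPM in RPMI8226. Cancer testis genes had medians of 0.15 over 4 (percentile 48.9, none 2-fold) and 0.63 over 16 (percentile 98.3, 7 higher and 1 lower), with MAGEC2 at 9.76 against 1.08 TPM in RPMI8226.

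A candidate explanation for the genes that were under 1 TPM in the RPMI8226 control and reached 2-fold and 1 TPM is that they belong to programs open to myeloma cells. Of 1097 genes under 1 TPM in the RPMI8226 control and at 1 TPM or above in the MM.1S control, 215 (19.6%) did so, against 455 of 10052 others (4.5%), a ratio of 4.33. Most of the genes that did so, 455 of 670, were also under 1 TPM in the MM.1S control, so their rise is not covered by this explanation. Among genes listed at 0 the ratio was 5.82, and among those above 0 and under 1 TPM it was 2.21. Genes already above 0 cross 1 TPM more easily, so part of the ratio may come from level alone. In MM.1S, with RPMI8226 as the other line, the ratio was 9.41. No cells other than myeloma lines were measured. The ratios therefore cannot tell programs of myeloma cells from genes expressed in many cell types. No mark on chromatin was measured, so how these genes were kept low was not tested.

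A further hypothesis was that RPMI8226 cells made interferon that could raise the interferon response genes. Of 21 type I and III interferon genes looked up, 0 were at 1 TPM or above and 2-fold higher with OR-S1 in RPMI8226, and 2 were above 0, the highest at 0.34 TPM. So low a level neither supports nor excludes this, since few transcripts are enough for a secreted factor and protein was not measured.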
